A study of Mus musculus with 32 samples.

How the data were processed

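RNA of 32 mouse liver samples, extracted with a column kit per the labels' protocols, was hybridised in 1 colour to arrays of 1 design, 8 to a slide on 4 slides. The deposited scanner files give each spot's processed intensity in linear units, made by Agilent Feature Extraction 11.5.1.1 with protocol GE1_1105_Oct12 per the file headers, whereas the submitters' processing notes name version 9.1. Each column of the deposited value table, in units the authors left unstated, was an array's scanner intensity times 1 constant (log2 range at most 3.32e-07). Its column medians ran from 57.9 to 80.3, with no centring of genes, and how the constant was chosen stays unknown. The file of 6-week control replicate 1 kept only 3 significant digits, leaving 4367 distinct intensities.

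Samples were grouped by title and age. Replicate 1 of the 20-week controls has 12 weeks in its source label and 20 weeks in title and age, and stayed with the 20-week group. Each array had 62976 spots, 59305 of them not controls, for 56605 probes. Outlier spots (51 to 140 per array) were left out and no spot was saturated. Gene symbols were matched through accessions for 32994 probes (58.3%). The log2 intensity minus each array's 75th percentile was averaged over spots of a probe, and the brightest probe stood for a gene. Features well above background on every array of at least 1 group were kept, 26590 of 45616. limma 3.58.1 in R 4.3.3 fitted all 9 groups (lmFit and eBayes, 23 residual and 2.92 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read files and drew plots.

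Before the data were examined, 42 gene lists (875 members, 827 measured), the groups, tests and alternatives were fixed. Lists were tested with camera at a correlation of 0.01, adjusted within each comparison, with an estimated correlation and fry, which does not compare a list with other genes, as alternatives. Named genes had a symbol, other than Gm, LOC, RIKEN or accession names, and were the 8 largest rises and falls per comparison with groups that did not overlap and the brighter group well above background, up to 4 called members per described list, up to 5 rises and 5 falls for differences between ages and for control ages, the 5 rises and falls with the largest mean among genes changed at all 4 ages, and members of the histone acetylation, pro-apoptotic and anti-apoptotic lists. Within that rule not every gene is given, some genes are not reported here, and which lists are described, and which with counts of members, was chosen after their results were seen. Probes of close paralogs such as Saa1 and Saa2 or Hamp and Hamp2 can bind both transcripts.

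Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, the deposited value table, other filters on dim probes, the mean of a gene's probes, slide as fixed or random block (consensus correlation 0.187), array weights, trend and robust moderation, only the compared groups, a 2-fold minimum, the doubly labelled control at 12 weeks and each array left out. Normexp used median foreground and background intensities in place of the planned mean column. In simulations with 200 changed features among 26590, 37.4% of 2-fold and 85.4% of 4-fold changes were recovered at 6 weeks. At 12 weeks 49.4% and 89.6% were, and between tumor and non-tumor tissue 49.4% and 88%. Of calls, 5.62%, 4.46% and 5.51% were false. Whether these hold at the spread of tumor arrays (median SD 0.476, non-tumor 0.236) was not tested.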

Results

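Gene expression was measured in livers of male C57BL/6J mice of the STAM model, in which neonatal streptozotocin followed by a high-fat diet leads from fatty liver to hepatocellular carcinoma, and in livers of control mice of the same ages. The 32 arrays fell into 9 groups. Controls were sampled at 6, 8, 12 and 20 weeks of age with 3, 3, 4 and 4 arrays. STAM livers were sampled at 6 weeks (steatosis, 3 arrays), 8 weeks (steatohepatitis, 3 arrays), 12 weeks (fibrosis, 4 arrays) and 20 weeks, when tumor and non-tumor tissue had 4 arrays each. The labels do not say that the replicates of a group are separate animals, so the p-values measure only the spread between these samples. Nor do they say whether tumor and non-tumor tissue came from the same mice. From 25886 (tumor replicate 3) to 41033 (tumor replicate 1) probes per array were well above background. The signal's 75th percentile was 158.5 to 1659, at 12 weeks 266 to 344 in control but 642 to 1021 in STAM. Replicates of a group correlated across genes at 0.9723 or more, except in tumor tissue (0.9412 to 0.9689). Control replicate 1 at 20 weeks, with 12 weeks in 1 label, is called the doubly labelled control. The number of arrays limits the precision.

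Changes below are log2 differences between group means with the standard error of the limma fit, over 26590 features, of which 16012 carried a gene symbol. Where a probe was not well above background on any array of the dimmer group, only a bound is given, as an "at least" fold: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. List counts are of measured members. Genes picked because their groups did not overlap move the same way within every slide by construction, so that agreement tests nothing for them. Normexp shrank 72 of the 213 named changes by over 1.5 times and turned none. Arbitrary splits of the same arrays gave 13 to 18 called lists at the median. With a correlation estimated from the data, the calls that held were lipid droplet, hepatocyte secreted protein, macrophage and interferon lists at 6 weeks, macrophages at 8 weeks, male-biased and hepatocyte secreted protein lists at 12 weeks, lipid droplets in non-tumor tissue and cell cycle in tumor tissue. The p53 and liver tumour lists held in all 5 comparisons with control, and no list held in the comparison of tumor with non-tumor tissue. Camera called 20, 25, 24, 29, 24 and 21 of the 42 lists in the 6 comparisons in turn, none of them the adipose, pancreatic or muscle markers (adjusted p 0.116 to 0.985).

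**Figure D1:**
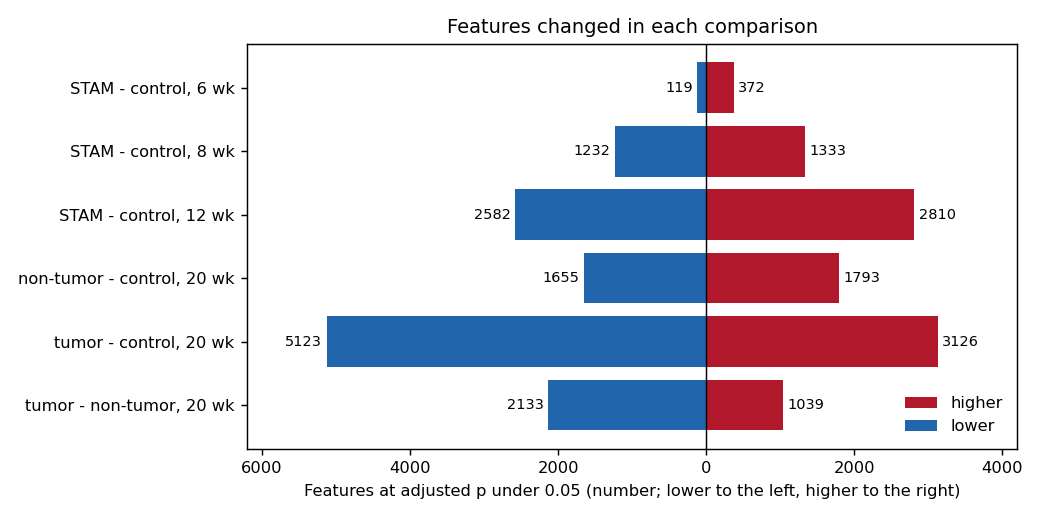
Number of features at an adjusted p under 0.05 in each of 6 comparisons, with lower features left and higher features right of 0. Counts run from 119 lower and 372 higher in STAM against control at 6 weeks to 5123 lower and 3126 higher in tumor tissue against control at 20 weeks.

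At the steatosis stage, 6-week STAM livers were compared with control (n = 3 arrays each). The imprinted RNA H19, made in fetal liver, rose by 6.58 ± 1.34 (95.5-fold), and the surface protein gene Ly6d rose by 5.81 ± 0.69 (56.2-fold). Rises were also seen in the fatty acid receptor Cd36 (3.07 ± 0.38, 8.42-fold), the lipid droplet proteins Cidea (4.48 ± 0.87) and Cidec (3.26 ± 0.62), the acyltransferase Mogat1 (3.38 ± 0.64) and the liver hormone Fgf21 (4.63 ± 0.85). Falls were seen in the SREBP anchor Insig1 (-1.50 ± 0.32), the desaturase Scd1 (-2.18 ± 0.50) and the androgen-regulated Kap (-4.96 ± 0.90, and -2.97 after normexp).

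Of 19 genes of lipid droplets and fat uptake, 4 rose and none fell, 15 did not pass, with 9 higher adjusted over the list alone, and camera placed them higher (adjusted p = 1.64e-10). Among the 24 genes of cholesterol synthesis and uptake, 3 fell and none rose, 21 did not pass (19 lower adjusted over the list alone), and camera placed them lower (adjusted p = 3.25e-14, adjusted p = 0.133 with an estimated correlation). The PPAR alpha target Vnn1 rose by 2.46 ± 0.39. Of 18 p53 targets, 6 rose and none fell, 12 did not pass, with 10 higher adjusted over the list alone, and camera placed them higher (adjusted p = 6.85e-15). They included the cyclin kinase inhibitor Cdkn1a (3.28 ± 0.57), Phlda3 (2.59 ± 0.27) and Eda2r, at least 5.62-fold higher. Among the 22 interferon-stimulated genes, 8 rose and none fell, 14 did not pass (18 higher adjusted over the list alone), and camera placed them higher (adjusted p = 8.87e-22). Oas1a and Ifi44 rose by 2.25 ± 0.35 and 2.23 ± 0.29. Of 21 macrophage markers, 6 rose and none fell, 15 did not pass, with 14 higher adjusted over the list alone, and camera placed them higher (adjusted p = 1.17e-12). Trem2, a lipid-sensing receptor of macrophages, rose by 2.08 ± 0.51, and Gpnmb was at least 2.1-fold higher. Among the 26 cytokine and chemokine genes, 5 rose and 1 fell, 20 did not pass (11 higher and 1 lower adjusted over the list alone), and camera placed them higher (adjusted p = 4.43e-11, adjusted p = 0.0763 with an estimated correlation). The monocyte attractant Ccl2 rose by 2.21 ± 0.50, while the brightest probe of Tnf fell (-2.14 ± 0.54) and its other probe changed by 1.32 the opposite way, so the direction of Tnf was not settled.

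Of 26 hepatocyte secreted proteins and identity factors, 1 fell and none rose, 25 did not pass, with 4 lower adjusted over the list alone, and camera placed them lower (adjusted p = 2.15e-07). Cyp2c70, which makes muricholic bile acids, changed by -2.12 ± 0.42. Camera also placed liver tumour genes, matrix genes, cell cycle genes and fatty acid oxidation genes higher (adjusted p = 3.25e-14, 1.17e-12, 5.28e-10 and 5.17e-08, and adjusted p = 3.76e-04, 0.169, 0.298 and 0.273 with an estimated correlation). Further rises at 6 weeks were Gldn (at least 15.8-fold), the angiotensin receptor Mas1 (at least 8.85-fold), Lrtm2 (at least 8.88-fold) and the BMP-binding protein Bmper (4.44 ± 0.70), and further falls were the dicarboxylate transporter Slc13a2 (-2.35 ± 0.50), the taurine synthesis enzyme Csad (-1.86 ± 0.42) and Nat8 (-1.86 ± 0.45). On the control arrays H19, Fgf21, Cidea and Cdkn1a were well above background on 2 of 3 and Bmper on 1 of 3, and Kap was on 1 of 3 STAM arrays.

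In all, 491 features changed, 372 higher and 119 lower, 360 of them by at least 2-fold, and the highest adjusted p among the named genes was 0.0422. With slide as a block 892 changed, all 28 named genes kept their calls, and within each of the 2 slides that held both groups all 28 moved the same way. The higher share of the calls was 75.8%, and 87.1% after quantile normalization, but 35.9% with array weights. The count fell to 102 without STAM replicate 3, 204 without STAM replicate 2, 294 without STAM replicate 1, and 311, 191 and 287 without control replicates 1, 2 and 3. Without STAM replicate 3, calls ended for H19, Gldn, Fgf21, Cidea, Slc13a2, Scd1, Tnf, Cyp2c70, Csad, Nat8, Cidec, Mogat1, Insig1, Trem2, Gpnmb and Ccl2 (adjusted p 0.0501 to 0.196). Some of these 16 genes also lost the call without STAM replicate 1 (4 genes, 0.0574 to 0.0973), STAM replicate 2 (6 genes, 0.0571 to 0.163), or control replicate 1 (8 genes, 0.0558 to 0.13), 2 (9 genes, 0.0539 to 0.129) or 3 (7 genes, 0.0635 to 0.154). The other 12 named genes, Ly6d, Cd36 and Cdkn1a among them, passed without any 1 array. Calls also ended after normexp for H19, Gldn, Lrtm2, Scd1, Csad, Trem2, Gpnmb and Ccl2 (adjusted p 0.0514 to 0.66), with only these groups for Cidea, Kap, Tnf, Cidec and Cdkn1a (0.0557 to 0.147), after quantile normalization for Slc13a2, Scd1 and Tnf (0.0537 to 0.0734), without a dim-probe filter for Tnf, Nat8, Trem2 and Gpnmb (0.0681 to 0.0937), with probe means for Tnf (0.781) and with slide and row for Nat8 (0.0649).

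At the steatohepatitis stage, 8-week STAM livers were compared with control (n = 3 arrays each). H19 rose by 8.41 ± 1.34 (340.1-fold), Ly6d by 7.82 ± 0.69 (227-fold), Cidea by 6.26 ± 0.87 and Fgf21 by 5.94 ± 0.85. The macrophage elastase Mmp12 was at least 23.4-fold higher, the collagenase Mmp13 at least 5.95-fold higher, and type I collagen Col1a1 rose by 3.25 ± 0.68 (9.51-fold), Trem2 by 3.66 ± 0.51 and Ccl2 by 3.51 ± 0.50. The male-specific steroid enzyme Hsd3b5 fell by 6.35 ± 1.07 on the log2 scale, and the cytochromes Cyp1a2 and Cyp2c37 changed by -3.20 ± 0.85 and -3.01 ± 0.82, the latter by -1.92 without STAM replicate 2.

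Among the 38 matrix genes, 21 rose and none fell, 17 did not pass (26 higher adjusted over the list alone), and camera placed them higher (adjusted p = 1.36e-18, adjusted p = 0.0891 with an estimated correlation). Of 21 macrophage markers, 12 rose and none fell, 9 did not pass, with 16 higher adjusted over the list alone, and camera placed them higher (adjusted p = 1.08e-15). Gpnmb was at least 8.17-fold higher. Among the 18 p53 targets, 13 rose and none fell, 5 did not pass (15 higher adjusted over the list alone), and camera placed them higher (adjusted p = 2.89e-20). Cdkn1a rose by 4.25 ± 0.57, the stress cytokine Gdf15 by 3.60 ± 0.37, and Eda2r was at least 9.99-fold higher. Of 37 cell cycle genes, 18 rose and none fell, 19 did not pass, with 27 higher adjusted over the list alone, and camera placed them higher (adjusted p = 5.77e-16, adjusted p = 0.136 with an estimated correlation). The helicase subunit Mcm5 rose by 2.12 ± 0.42 and cyclin D1, Ccnd1, by 2.07 ± 0.35. The biliary marker Anxa2 rose by 2.78 ± 0.40. Cidec rose by 4.48 ± 0.62. Camera also placed biliary markers, liver tumour genes, cytokines, interferon-stimulated genes and lipid droplet genes higher (adjusted p = 1.88e-07, 1.34e-14, 2.31e-13, 7.86e-12 and 2.24e-06, and adjusted p = 0.0546, 3.28e-04, 0.0546, 0.136 and 0.128 with an estimated correlation). Cholesterol genes and hepatocyte secreted proteins were placed lower (adjusted p = 7.19e-06 and 7.08e-05, and adjusted p = 0.483 and 0.0859 with an estimated correlation).

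Among the 18 male-biased liver genes, 6 fell and none rose, 12 did not pass (8 lower adjusted over the list alone), and camera placed them lower (adjusted p = 2.52e-05, adjusted p = 0.19 with an estimated correlation). Of 22 drug-metabolising cytochromes, 8 fell and none rose, 14 did not pass, with 11 lower adjusted over the list alone, and camera placed them lower (adjusted p = 2.20e-06, adjusted p = 0.115 with an estimated correlation). Other large rises were Psrc1 (at least 22.3-fold), Gldn (at least 18.7-fold) and Bmp8b (at least 16.1-fold), and other large falls were Serpina4-ps1 (-4.24 ± 0.87), Slc13a2 (-4.04 ± 0.50), Nat8 (-3.90 ± 0.45), Nat8f6 (-3.31 ± 0.50), Cnmd (-3.79 ± 0.76), the retinoic acid hydroxylase Cyp26a1 (10.6-fold lower, adjusted p = 0.0307) and the homeobox gene Irx1, at least 5.36-fold lower. Of the control arrays, 2 of 3 had H19, Fgf21 and Cdkn1a well above background and 1 of 3 had Cidea; Nat8f6 was on 2 of 3 STAM arrays.

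At this age 2565 features changed, 1333 higher and 1232 lower, 1497 by at least 2-fold, with 3065 when slide was a block. The higher share was 52%, and 64.2% and 69.3% after normexp and after quantile normalization, but 34.9% with array weights and 42.1% among genes well above background on all arrays. Within the 2 slides that held both groups all 30 named genes moved the same way. The count fell to 904 without STAM replicate 2, 1594 without STAM replicate 1, 1383 without control replicate 2 and 1434 without control replicate 3. Calls ended for Cyp26a1 without any control replicate or STAM replicate 1 or 2 (adjusted p 0.0687 to 0.185), for Cyp1a2 without control replicate 2 or 3 or STAM replicate 1 or 2 (0.0583 to 0.103), for Cyp2c37 without any control replicate or STAM replicate 2 (0.0524 to 0.199), and for Irx1 without STAM replicate 2 (0.0557). Only the 2 groups in the fit gave 1309 features. Calls also ended after normexp for Gldn, Irx1 and Cyp2c37 (adjusted p 0.0544 to 0.177), with only these groups for Cnmd, Ccnd1 and Cyp2c37 (0.0536 to 0.0987), after quantile normalization for Cyp26a1 and Cyp2c37 (0.0512 to 0.0585), without a dim-probe filter for Cyp26a1 (0.0639), with the slide block for Cyp26a1 (0.0524) and with slide and row for Cyp26a1 (0.063).

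At the fibrosis stage, 12-week STAM livers were set against control (n = 4 arrays each). In genes that male mouse liver expresses strongly, Hsd3b5 changed by -10.38 ± 0.93 and the organic anion transporter Slco1a1 by -9.02 ± 1.17, while Cyp2b13, a female-biased cytochrome, rose by 6.50 ± 0.88 (90.4-fold), but by 4.199 after normexp. The iron hormone hepcidin, Hamp, changed by -6.44 ± 1.36 and its paralog Hamp2 by -4.74 ± 0.86. Cdkn1a rose by 5.71 ± 0.49 (52.2-fold), and the kinase Pdk4, which spares glucose, and the mitochondrial thioesterase Acot2 rose by 5.10 ± 0.59 and 4.72 ± 0.39. Ly6d (7.30 ± 0.60), H19 (6.33 ± 1.16), Fgf21 (5.92 ± 0.74) and Cidea (5.62 ± 0.76) were again higher.

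Among the 18 male-biased genes, 16 fell and none rose, 2 did not pass (17 lower adjusted over the list alone), and camera placed them lower (adjusted p = 1.50e-11). Of 20 female-biased genes, 6 rose and 3 fell, 11 did not pass, with 10 higher and 3 lower adjusted over the list alone, and camera placed them higher (adjusted p = 0.0049, adjusted p = 0.264 with an estimated correlation). The sulfotransferase Sult2a1 was at least 6.74-fold higher. The female-biased call ended when only genes well above background on all arrays were tested (adjusted p = 0.678). Among the 27 genes of fatty acid oxidation, 16 rose and 2 fell, 9 did not pass (17 higher and 2 lower adjusted over the list alone), and camera placed them higher (adjusted p = 1.93e-08, adjusted p = 0.264 with an estimated correlation). Of 22 drug-metabolising cytochromes, 1 rose and 7 fell, 14 did not pass, with 2 higher and 8 lower adjusted over the list alone, and camera placed them lower (adjusted p = 0.00726, adjusted p = 0.366 with an estimated correlation). Among the 26 hepatocyte secreted proteins, 14 fell and none rose, 12 did not pass (1 higher and 14 lower adjusted over the list alone), and camera placed them lower (adjusted p = 3.79e-06). Coagulation factor XI, F11, changed by -2.35 ± 0.25 and albumin, Alb, by -1.30 ± 0.39, but by -0.06 after quantile normalization and -0.03 after normexp. The cytochrome and secreted protein lists lost their calls under quantile normalization (adjusted p = 0.122 and 0.113) and normexp (0.121 and 0.107). Camera also placed macrophage markers, liver tumour genes, lipid droplet genes, matrix genes, cell cycle genes and interferon-stimulated genes higher (adjusted p = 2.77e-10, 2.19e-11, 2.85e-09, 1.45e-07, 3.64e-08 and 4.45e-09, and adjusted p = 0.0642, 0.0015, 0.059, 0.33, 0.34 and 0.256 with an estimated correlation).

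Of 18 p53 targets, 12 rose and none fell, 6 did not pass, with 14 higher adjusted over the list alone, and camera placed them higher (adjusted p = 2.29e-16). Among the 12 Kupffer cell markers, 8 rose and none fell, 4 did not pass (8 higher adjusted over the list alone), and camera placed them higher (adjusted p = 4.37e-05, adjusted p = 0.34 with an estimated correlation). The scavenger receptor Marco rose by 3.40 ± 0.61. Of 14 neutrophil markers, 7 rose and none fell, 7 did not pass, with 8 higher adjusted over the list alone, and camera placed them higher (adjusted p = 2.60e-04, adjusted p = 0.264 with an estimated correlation). S100a8 rose by 4.42 ± 0.78. This list's call ended among genes well above background on all arrays (adjusted p = 0.633). Among the 7 erythroid markers, 5 rose and 2 fell (5 higher and 2 lower adjusted over the list alone), and camera placed them higher (adjusted p = 0.0152, adjusted p = 0.444 with an estimated correlation). The beta globin Hbb-bt rose by 3.11 ± 0.59.

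Of 35 pro-apoptotic and death receptor genes, 14 rose and 5 fell, 16 did not pass, with 14 higher and 5 lower adjusted over the list alone, and camera placed them higher (adjusted p = 0.0016, adjusted p = 0.264 with an estimated correlation). The TRAIL receptor Tnfrsf10b rose by 2.12 ± 0.39, the necroptosis kinase Ripk3 by 1.79 ± 0.29 and the apoptosome scaffold Apaf1 by 1.54 ± 0.20. Among the 16 anti-apoptotic genes, 2 rose and none fell, 14 did not pass (2 higher adjusted over the list alone), and camera did not call them (adjusted p = 0.0699). Tnfaip8 rose by 1.14 ± 0.29 and Naip1 was at least 1.53-fold higher, while Bcl2 (0.85 ± 0.40, adjusted p = 0.136) and Naip2 (0.62 ± 0.27, adjusted p = 0.109) did not pass, except with array weights or only these groups (adjusted p 0.00989 to 0.0443). The list passed under 5 other settings of camera (0.00507 to 0.039) and without control replicate 3 (0.0322) or STAM replicate 3 (0.0395). Of 28 histone acetylation enzymes, 2 rose and 2 fell, 24 did not pass, with 2 higher and 2 lower adjusted over the list alone, and camera did not call them (adjusted p = 0.648). The deacetylases Hdac9 (0.89 ± 0.24) and Hdac8 (0.68 ± 0.23) rose and the sirtuins Sirt6 (-0.57 ± 0.20) and Sirt7 (-0.47 ± 0.16) fell, all by less than 2-fold. Hdac8 lost its call without control replicate 1 or 2 or STAM replicate 1, 2 or 3 (adjusted p 0.0593 to 0.127), Sirt6 without control replicate 1, 2 or 4 or STAM replicate 1 or 2 (0.0646 to 0.155), and Sirt7 without control replicate 2, 3 or 4 or STAM replicate 2, 3 or 4 (0.0533 to 0.098).

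Among the 17 clock genes, 3 rose and 7 fell, 7 did not pass (4 higher and 9 lower adjusted over the list alone), and camera did not call them (adjusted p = 0.0674). The clock activator Arntl rose by 2.97 ± 0.53 and its output Dbp fell by 2.87 ± 0.43 on the log2 scale. Without STAM replicate 1 the clock list passed (adjusted p = 0.00353). Other large changes were Lrtm2 (at least 22.4-fold higher), Dmbt1 (at least 19-fold higher), the adrenergic receptor Adra2a (at least 18-fold higher), Clec2h (-5.88 ± 0.78), Adgrf1 (-5.45 ± 1.06) and Serpina4-ps1 (-5.08 ± 0.76). Cyp2b13 was well above background on 1 of 4 control arrays, H19 and Cdkn1a on 2 of 4, and Fgf21, Cidea, S100a8 and Tnfrsf10b on 3 of 4, whereas Slco1a1 and Adgrf1 were on 2 and Hsd3b5, Clec2h and Serpina4-ps1 on 3 of 4 STAM arrays.

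In total 5392 features changed at 12 weeks, 2810 higher and 2582 lower, 2582 of them by at least 2-fold, and 7985 with slide as a block. The higher share was 52.1%, and 61.8% after quantile normalization, but 42.5% with the block. All 35 named genes that passed kept their calls with the block, and moved the same way within each of the 4 slides. The count was 3563 without STAM replicate 2. Besides the deacetylases and sirtuins above, calls ended for Dmbt1 without STAM replicate 1 (adjusted p = 0.0722) and for Alb without control replicate 1 or STAM replicate 1 or 2 (adjusted p 0.052 to 0.0637). Calls also ended after normexp for Alb, Hdac8 and Sirt7 (adjusted p 0.0525 to 0.838), after quantile normalization for Alb, Hdac8 and Sirt7 (0.0573 to 0.677), without a dim-probe filter for Hdac8, Sirt6 and Sirt7 (0.0779 to 0.0842), with probe means for Hdac8 (0.0626) and with the doubly labelled control at 12 weeks for Hdac8 and Sirt6 (0.0523 to 0.0539).

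**Figure D2:**
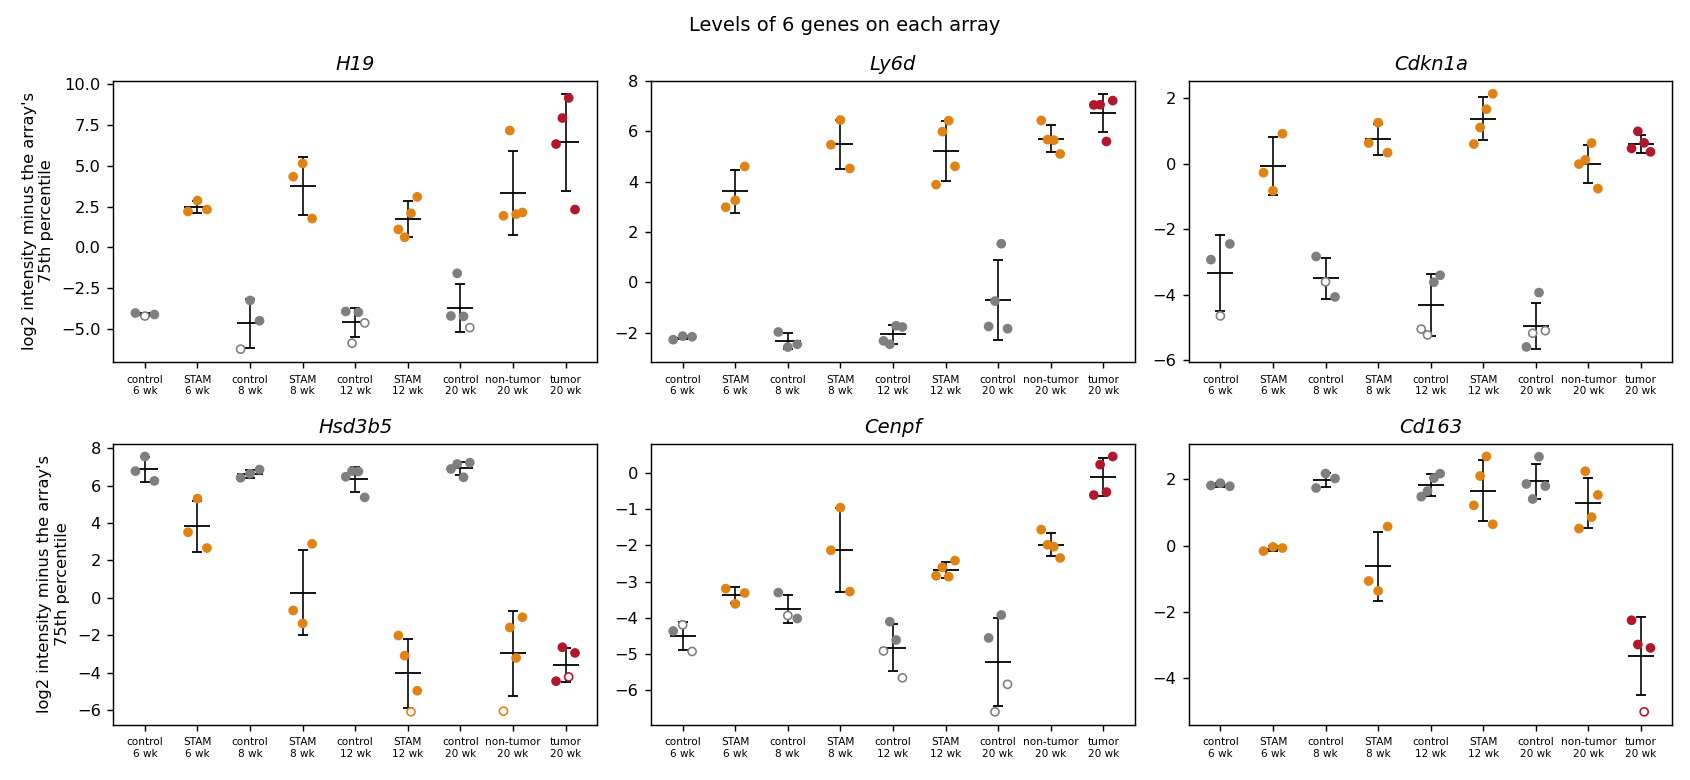
Levels of 6 genes on each of the 32 arrays, as log2 intensity minus the array's 75th percentile, by group. Filled points were well above background and open points were not, and bars mark the group mean and its standard deviation over 3 or 4 arrays. H19, Ly6d and Cdkn1a lie higher in every STAM group than in control of the same age, Hsd3b5 lies lower, and Cd163 lies lowest in tumor tissue.

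At 20 weeks, non-tumor STAM tissue was compared with control liver (n = 4 arrays each). Cidea rose by 7.55 ± 0.76 (187-fold), and the related Cidec rose by 5.23 ± 0.53 (37.6-fold), H19 by 7.05 ± 1.16, Ly6d by 6.42 ± 0.60 and Cdkn1a by 4.95 ± 0.49 (2.68 after normexp). Cell cycle genes rose: the kinetochore gene Cenpf by 3.25 ± 0.45 (1.13 after normexp) and the mitotic regulator Cdc20 by 2.73 ± 0.40. Hsd3b5 changed by -9.89 ± 0.93 and Hamp by -5.48 ± 1.36, and the acute-phase gene Saa2 by -2.67 ± 0.78.

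Of 37 cell cycle genes, 31 rose and none fell, 6 did not pass, with 33 higher adjusted over the list alone, and camera placed them higher (adjusted p = 1.37e-28, adjusted p = 0.0538 with an estimated correlation). Among the 19 genes of lipid droplets and fat uptake, 12 rose and none fell, 7 did not pass (13 higher and 1 lower adjusted over the list alone), and camera placed them higher (adjusted p = 7.61e-13). Of 18 p53 targets, 12 rose and none fell, 6 did not pass, with 13 higher adjusted over the list alone, and camera placed them higher (adjusted p = 3.99e-15). Phlda3 rose by 3.46 ± 0.24. The carbonyl reductase Cbr3 rose by 4.64 ± 0.61. The MHC class II gene H2-Eb1 rose by 1.48 ± 0.35. Gpnmb was at least 7.8-fold higher. Ccl2 and Mmp13 rose by 2.58 ± 0.44 and 4.05 ± 0.64. Camera also placed MHC class II genes, cytokines, macrophage markers, matrix genes and liver tumour genes higher (adjusted p = 2.34e-09, 1.26e-08, 6.52e-11, 1.38e-09 and 7.33e-19, and adjusted p = 0.131, 0.135, 0.0538, 0.239 and 4.30e-05 with an estimated correlation).

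Among the 25 acute-phase proteins, 10 fell and none rose, 15 did not pass (14 lower adjusted over the list alone), and camera placed them lower (adjusted p = 5.87e-06, adjusted p = 0.265 with an estimated correlation). The mean shift of these acute-phase proteins was -1.17, and -0.60 without control replicate 3 (adjusted p = 0.0152), whose level was 7.94 against 5.36 to 5.88 on the other 3 controls. Of 18 male-biased genes, 8 fell and none rose, 10 did not pass, with 13 lower adjusted over the list alone, and camera placed them lower (adjusted p = 8.48e-07, adjusted p = 0.135 with an estimated correlation). Among the 20 female-biased genes, 7 rose and 3 fell, 10 did not pass (9 higher and 3 lower adjusted over the list alone), and camera placed them higher (adjusted p = 6.92e-04, adjusted p = 0.171 with an estimated correlation). Of 26 hepatocyte secreted proteins, 10 fell and none rose, 16 did not pass, with 15 lower adjusted over the list alone, and camera placed them lower (adjusted p = 1.24e-05, adjusted p = 0.0538 with an estimated correlation). Among genes well above background on all arrays the female-biased call ended (adjusted p = 0.214), and under quantile normalization the secreted protein call ended (adjusted p = 0.196) as it did after normexp (0.158). Other large changes were Gldn (at least 22.4-fold higher), Bmp8b (at least 30.0-fold higher), Lrtm2 (at least 18.1-fold higher), Krt20 (at least 9.97-fold higher), the tubulin Tubb2b (5.55 ± 0.74), Cyp26a1 (-4.78 ± 0.87), Obp2a (-4.12 ± 0.82), Adgrf1 (-3.90 ± 1.06), Capn8 (-3.74 ± 0.67) and Slco1a1 (-3.73 ± 1.17). On control arrays Tubb2b and Mmp13 were well above background on 1 of 4, Cenpf and Cdkn1a on 2 of 4 and H19 on 3 of 4. On non-tumor arrays Capn8 was on 1, Obp2a on 2 and Hsd3b5 and Adgrf1 on 3 of 4.

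This comparison gave 3448 changed features, 1793 higher and 1655 lower, 1820 by at least 2-fold, and 5655 with slide as a block, which ended none of the 27 named calls. The higher share was 52%, but 39.8% with the block. Within the 4 slides 26 of the 27 moved the same way, and Saa1 (-2.25 ± 0.72) did so in 3 of 4. Calls ended for Adgrf1 without non-tumor replicate 3 (adjusted p = 0.0528), for Slco1a1 without control replicate 1, 2 or 4 or non-tumor replicate 1, 2 or 3 (adjusted p 0.0618 to 0.134), for Saa2 without control replicate 1 or 3 or non-tumor replicate 2 or 3 (0.0522 to 0.0965) and for Saa1 without the same arrays or non-tumor replicate 1 (0.0598 to 0.145). Calls also ended without a dim-probe filter for Slco1a1 and Saa1 (adjusted p 0.0657 to 0.0741), with the doubly labelled control at 12 weeks for Slco1a1, Saa2 and Saa1 (0.0556 to 0.14), with slide and row for Slco1a1 and Saa1 (0.0546 to 0.0602), after normexp for Saa1 (0.073), after quantile normalization for Saa1 (0.0796) and with only these groups for Saa1 (0.0686).

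Tumor tissue was compared with control liver at 20 weeks (n = 4 arrays each). H19 rose by 10.17 ± 1.16 (1153-fold), Tubb2b by 8.66 ± 0.74 (404-fold, but 5.38 after normexp) and Ly6d by 7.44 ± 0.60. Mitotic genes rose, with Cenpf at 5.13 ± 0.45 (2.63 after normexp), Cdc20 at 4.63 ± 0.40 and the survivin gene Birc5 at 3.68 ± 0.30. Enzymes of nitrogen disposal fell, among them the histidine ammonia lyase Hal (-4.96 ± 0.56) and the serine dehydratase Sds (-4.09 ± 0.81), as did the resident macrophage genes Cd163 (-5.26 ± 0.48) and Timd4 (-3.71 ± 0.35). Hsd3b5 changed by -10.49 ± 0.93.

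Among the 37 cell cycle genes, 37 rose and none fell (37 higher adjusted over the list alone), and camera placed them higher (adjusted p = 1.01e-40). Of 30 liver tumour and fetal liver genes, 21 rose and none fell, 9 did not pass, with 21 higher adjusted over the list alone, and camera placed them higher (adjusted p = 1.04e-13). Among the 18 p53 targets, 13 rose and 2 fell, 3 did not pass (14 higher and 2 lower adjusted over the list alone), and camera placed them higher (adjusted p = 4.13e-10). Uhrf1, a cofactor of maintenance methylation, rose by 4.22 ± 0.50. Cidea and Col1a1 rose by 6.41 ± 0.76 and 4.03 ± 0.59. Camera also placed DNA and histone methylation enzymes, lipid droplet genes and matrix genes higher (adjusted p = 0.0207, 3.31e-09 and 1.38e-10, and adjusted p = 0.224, 0.0625 and 0.224 with an estimated correlation). Drug-metabolising cytochromes and hepatocyte secreted proteins were placed lower (adjusted p = 2.41e-05 and 5.47e-06, and adjusted p = 0.188 and 0.0531 with an estimated correlation). Of 21 macrophage markers, 11 rose and 3 fell, 7 did not pass, with 11 higher and 3 lower adjusted over the list alone, and camera placed them higher (adjusted p = 8.93e-05, adjusted p = 0.243 with an estimated correlation). Gpnmb was at least 21.4-fold higher. Among the 12 Kupffer cell markers, 1 rose and 11 fell (1 higher and 11 lower adjusted over the list alone), and camera placed them lower (adjusted p = 9.40e-09, adjusted p = 0.188 with an estimated correlation). The riser, named after its value was seen, was the stress-induced heme oxygenase Hmox1 (0.67 ± 0.24). Of 18 endothelial markers, 5 rose and 6 fell, 7 did not pass, with 6 higher and 7 lower adjusted over the list alone, and camera did not call them (adjusted p = 0.85). Its median was -0.14 while its test pointed up, and Cd34 rose by 3.43 ± 0.26.

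Among the 24 genes of the urea cycle and amino acid breakdown, 22 fell and none rose, 2 did not pass (23 lower adjusted over the list alone), and camera placed them lower (adjusted p = 2.56e-10, adjusted p = 0.179 with an estimated correlation). Of 15 periportal hepatocyte genes, 13 fell and none rose, 2 did not pass, with 13 lower adjusted over the list alone, and camera placed them lower (adjusted p = 5.76e-07, adjusted p = 0.243 with an estimated correlation). Among the 16 pericentral hepatocyte genes, 2 fell and none rose, 14 did not pass (2 lower adjusted over the list alone), and camera did not call them (adjusted p = 0.93). That list turned upward and passed without tumor replicate 3 (adjusted p = 0.00843), and passed as lower without tumor replicate 4 (0.0454). Cyp2f2 changed by -3.85 ± 0.46. Of 18 male-biased genes, 16 fell and none rose, 2 did not pass, with 16 lower adjusted over the list alone, and camera placed them lower (adjusted p = 4.40e-09, adjusted p = 0.0817 with an estimated correlation). Among the 20 female-biased genes, 9 rose and 4 fell, 7 did not pass (11 higher and 5 lower adjusted over the list alone), and camera placed them higher (adjusted p = 0.00746, adjusted p = 0.272 with an estimated correlation). The hydroxyacid oxidase Hao2 was at least 37.1-fold higher. This call ended among genes well above background on all arrays (adjusted p = 0.898). Of 25 acute-phase proteins, 19 fell and none rose, 6 did not pass, with 19 lower adjusted over the list alone, and camera placed them lower (adjusted p = 3.79e-07, adjusted p = 0.234 with an estimated correlation). Saa2 and Orm1 changed by -5.58 ± 0.78 and -4.48 ± 0.57.

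Among the 28 histone acetylation enzymes, 3 rose and 6 fell, 19 did not pass (3 higher and 6 lower adjusted over the list alone), and camera did not call them (adjusted p = 0.866). The histone acetyltransferase Hat1 rose by 1.01 ± 0.21, and Sirt7 (-0.86 ± 0.16), Hdac7 (-1.03 ± 0.36, and -0.65 without tumor replicate 2) and Hdac9 (-0.84 ± 0.24) fell, although other Hdac9 probes changed by -0.33 to 0.17 and Hdac7 fell within 3 of 4 slides. Median and test differed in sign here (median -0.02). Of 35 pro-apoptotic genes, 9 rose and 5 fell, 21 did not pass, with 9 higher and 6 lower adjusted over the list alone, and camera did not call them (adjusted p = 0.146). Its median, -0.08, also lay on the other side of 0 from its test. Tnfrsf10b rose by 3.40 ± 0.39, while Bmf (-3.27 ± 0.41) and Bik (-1.57 ± 0.32), which trigger death by binding Bcl2 proteins, fell. Among the 16 anti-apoptotic genes, 3 rose and 4 fell, 9 did not pass (4 higher and 5 lower adjusted over the list alone), and camera did not call them (adjusted p = 0.442). Bcl2 rose by 1.43 ± 0.40 (0.72 without tumor replicate 3), Birc3 changed by -0.76 ± 0.25, and Naip1 was at least 1.42-fold lower, in 3 of 4 slides (-0.83 as the mean of its probes). Calls ended for Hdac7 without control replicate 2 or 3 or tumor replicate 1 or 2 (adjusted p 0.0665 to 0.183) and for Birc3 without control replicate 3 or 4 or tumor replicate 2 or 3 (0.0552 to 0.0937). Calls also ended with only these groups for Sds, Sirt7, Hdac7, Hdac9, Bcl2, Birc3 and Gnmt (adjusted p 0.0559 to 0.173), after quantile normalization for Hdac7 (0.0556), without a dim-probe filter for Hdac7 and Birc3 (0.0503 to 0.063), with array weights for Hdac7, Hdac9 and Birc3 (0.0528 to 0.222) and with probe means for Hdac9 (0.257).

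Other large rises were Sdcbp2 (7.67 ± 0.81), the fatty acid elongase Elovl7 (7.29 ± 0.72), Gldn (at least 37.7-fold), Bmp8b (at least 53.2-fold) and the retinol-binding Rbp7 (at least 58.2-fold). Other large falls were Clec2h (-7.70 ± 0.78), Slco1a1 (-7.03 ± 1.17), Cyp26a1 (-6.57 ± 0.87), Sult5a1 (-6.01 ± 0.34), Tiam2 (-5.80 ± 0.57) and Obp2a (at least 18.6-fold). Tubb2b and Elovl7 were well above background on 1, Sdcbp2 and Cenpf on 2 and H19 on 3 of the 4 control arrays, and Clec2h on 1, Sult5a1 on 2 and Hsd3b5, Slco1a1, Cyp26a1, Cd163, Timd4 and Hdac9 on 3 of the 4 tumor arrays.

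Tumor tissue differed from control in 8249 features, 3126 higher and 5123 lower, 4293 of them by at least 2-fold, with 10433 when slide was a block and 3694 with only the 2 groups in the fit. The block ended no call of the 47 named genes, and 45 of them moved the same way on all 4 slides. The higher share was 37.9%, and 49.4% and 47.6% after normexp and after quantile normalization. The median change of all features was -0.15, and -0.04 after normexp, so small changes in tumor tissue are read against that shift.

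**Figure D3:**
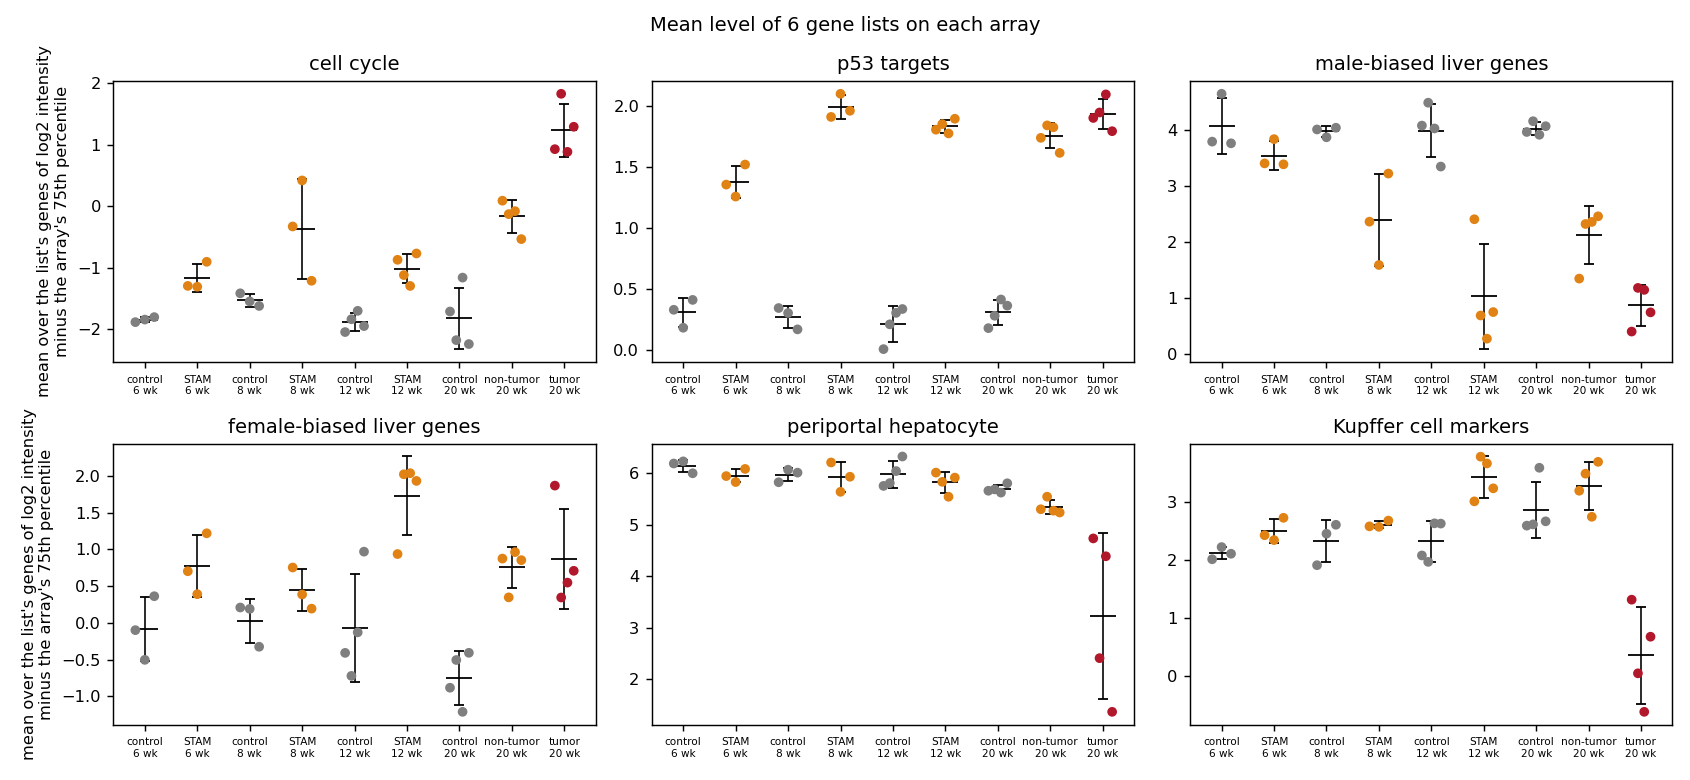
Mean level of 6 gene lists on each array, in log2 intensity minus the array's 75th percentile, by group, with the group mean and standard deviation over 3 or 4 arrays. Cell cycle genes lie highest and periportal and Kupffer cell genes lowest in tumor tissue.

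Tumor tissue was then compared with non-tumor tissue (n = 4 arrays each). Resident macrophage genes fell, with Marco at -5.03 ± 0.61, Cd163 at -4.62 ± 0.48 and Timd4 at -3.95 ± 0.35. The tumor-associated genes Gpc3 (2.85 ± 0.56, 7.2-fold) and Igf2 (3.52 ± 1.13, and 1.90 without tumor replicate 3) rose, as did mitotic genes such as Ccnb2 (2.01 ± 0.29) and Cdc25c (2.31 ± 0.55), and Cd34, a marker of capillary endothelium, rose by 1.85 ± 0.26. Hal (-3.38 ± 0.56), the urocanase Uroc1 (-2.94 ± 0.46) and the gluconeogenic enzyme Pck1 (-2.25 ± 0.33) fell.

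Of 12 Kupffer cell markers, 11 fell and none rose, 1 did not pass, with 12 lower adjusted over the list alone, and camera placed them lower (adjusted p = 2.33e-21, adjusted p = 0.0894 with an estimated correlation). Among the 21 macrophage markers, 1 rose and 4 fell, 16 did not pass (3 higher and 5 lower adjusted over the list alone), and camera did not call them (adjusted p = 0.778). The macrophage list's median was 0.05 and its test pointed down, and Csf1r, the receptor of the macrophage growth factor, fell by 1.84 ± 0.24 on the log2 scale, with -1.18 as the mean of its probes. Of 18 endothelial markers, 1 rose and 9 fell, 8 did not pass, with 1 higher and 10 lower adjusted over the list alone, and camera placed them lower (adjusted p = 1.68e-04, adjusted p = 0.489 with an estimated correlation). The sinusoidal lectin Clec4g changed by -2.12 ± 0.29. Among the 17 stellate cell and myofibroblast markers, 1 rose and 7 fell, 9 did not pass (3 higher and 9 lower adjusted over the list alone), and camera placed them lower (adjusted p = 0.0408, adjusted p = 0.591 with an estimated correlation). The retinol-storing enzyme Lrat (-1.94 ± 0.25) and the hedgehog-binding Hhip (-3.70 ± 0.37) fell. The stellate call ended without tumor replicate 1, 2 or 4 (adjusted p = 0.165, 0.174 and 0.209) or non-tumor replicate 1 or 2 (0.0879 and 0.0596) and after normexp (0.075), with the mean of a gene's probes (0.0616) and among genes well above background on all arrays (0.112).

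Of 37 cell cycle genes, 32 rose and none fell, 5 did not pass, with 36 higher adjusted over the list alone, and camera placed them higher (adjusted p = 2.26e-28, adjusted p = 0.116 with an estimated correlation). Among the 24 genes of cholesterol synthesis and uptake, 9 rose and none fell, 15 did not pass (16 higher adjusted over the list alone), and camera placed them higher (adjusted p = 2.89e-09, adjusted p = 0.352 with an estimated correlation). The mevalonate pathway enzyme Mvd rose by 1.83 ± 0.45. Of 24 genes of the urea cycle and amino acid breakdown, 18 fell and none rose, 6 did not pass, with 22 lower adjusted over the list alone, and camera placed them lower (adjusted p = 2.29e-13, adjusted p = 0.146 with an estimated correlation). Among the 15 periportal genes, 11 fell and none rose, 4 did not pass (13 lower adjusted over the list alone), and camera placed them lower (adjusted p = 7.56e-11, adjusted p = 0.226 with an estimated correlation). Of 16 pericentral genes, no member rose or fell, 16 did not pass, with none adjusted over the list alone, and camera did not call them (adjusted p = 0.836). Without tumor replicate 3 the pericentral list passed as higher (adjusted p = 9.13e-05) and without tumor replicate 4 as lower (0.00623). Uhrf1 rose by 1.74 ± 0.50. Camera also placed DNA and histone methylation enzymes higher (adjusted p = 6.57e-04, and adjusted p = 0.116 with an estimated correlation).

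Other rises were the prion-like Prnd (4.36 ± 0.77), Hao2 (4.25 ± 0.77), the vascular peptide Apln (3.42 ± 0.45), the histone gene H3c8 (3.14 ± 0.54) and Akr1b7 (2.98 ± 0.69). Other falls were Sult2a7 (-5.38 ± 0.74), Gbp2b (-4.34 ± 0.47), the eosinophil attractant Ccl24 (-4.22 ± 0.50), Tmprss4 (-4.17 ± 0.61), the nicotinamide methyltransferase Nnmt (-3.31 ± 0.55) and Cfd (-4.36 ± 1.35). Prnd, Hao2 and H3c8 were well above background on 2 of 4 non-tumor arrays, Hhip on 1 and Cd163, Timd4, Gbp2b, Ccl24, Tmprss4 and Cfd on 3 of 4 tumor arrays.

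The tissues differed in 3172 features, 1039 higher and 2133 lower in tumor, 1636 by at least 2-fold, with 4555 when slide was a block. All 28 named genes passed with the block. They kept direction within each of the 4 slides, by construction for those picked because the groups did not overlap. However, all tumor arrays sat in the first row of their slide and all non-tumor arrays in the second. The higher share was 32.8%, and 49.4% and 45.4% after normexp and after quantile normalization. The count was 5108 without tumor replicate 1, 1857 without tumor replicate 2 and 2086 without non-tumor replicate 2, and 372 with only these 8 arrays in the fit. Calls ended for Cfd without tumor replicate 2 or 3 or non-tumor replicate 1, 2 or 4 (adjusted p 0.0667 to 0.116), for Igf2 without tumor replicate 2 or 3 or non-tumor replicate 1, 3 or 4 (0.0972 to 0.21) and for Uhrf1 without tumor replicate 2 or non-tumor replicate 2 or 4 (0.0552 to 0.126). Calls also ended with only these groups for Prnd, Hao2, Akr1b7, Cfd, Tmprss4, Gpc3, Igf2, Hal, Uroc1, Pck1, Clec4g, Mvd, Nnmt and Uhrf1 (adjusted p 0.0501 to 0.396), without a dim-probe filter for Cfd and Igf2 (0.0679 to 0.0821), with array weights for Cfd, Igf2, Cdc25c, Mvd and Uhrf1 (0.0793 to 0.166), with probe means for Igf2 (0.0519) and with slide and row for Igf2 (0.0791).

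In both 20-week STAM tissues against control, 1254 features were higher and 1376 lower, where independent lists of these sizes would share 211 and 319. Another 24 changed in opposite directions. Simulated unchanged groups against shared controls shared no called feature, which cannot show what real controls add, since unchanged groups give few calls. Their changes had a covariance of 0.0533 (observed 0.535) and a correlation of 0.5 (observed 0.782). With the controls split between the comparisons, 2 arrays to each, in all 6 ways, the shared features numbered 970 to 1474, and the covariance was 0.444 to 0.512. With slide as a block 4134 features were shared.

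Across the STAM livers without tumor, 269 features were higher and 46 lower at all of 6, 8, 12 and 20 weeks, against 0.133 and 0.0333 for independent lists. The largest mean rises over these ages were in H19 (7.09), Ly6d (6.84), Gldn, Cidea (5.98) and Bmp8b, and, among features with a symbol of the kind named here, the largest mean falls in Nat8 (-3.21), the brightest probe of Tnf (-2.90, its other probe rising), Slc13a2 (-2.89), the peptidase gene Trhde and the adhesion gene Cadm4 (-2.22). Gldn, Bmp8b and Trhde, not well above background in 1 group at some or all ages, have no mean or settled rank. Ly6d and Bmp8b passed at all 4 ages without any 1 array. The other 8 did not without 1 array of the 6-week or, for Tnf and Trhde, also of the 8-week groups (adjusted p 0.0508 to 0.196), STAM replicate 3 at 6 weeks in each case. Calls at 1 or more ages also ended after normexp for H19, Gldn, Bmp8b and Trhde (adjusted p 0.0514 to 0.297), without a dim-probe filter for Nat8, Tnf, Trhde and Cadm4 (0.0682 to 0.0871), with slide and row for Nat8, Trhde and Cadm4 (0.0524 to 0.0769), after quantile normalization for Tnf and Slc13a2 (0.0537 to 0.0552), with probe means for Tnf (0.781) and with the slide block for Cadm4 (0.0502). With slide as a block both directions together numbered 514, not 315. It was 86 without 6-week STAM replicate 3, 164 without 6-week STAM replicate 2, and 141 and 187 without 6-week control replicates 2 and 3.

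Whether the STAM effect itself changed with age was tested as a difference of differences. Between 8 and 12 weeks 15 features differed, 9 higher and 6 lower, and 29 with slide as a block. The effect on Arntl was higher at 12 weeks by 4.18 ± 0.81, that on Lrfn3 by 2.73 ± 0.47, on the troponin Tnnc1 by 2.64 ± 0.51, on Gtf2ird1 by 1.39 ± 0.23 and on Klhl7 by 1.22 ± 0.21 (n = 3 and 4 arrays per group). By limma the number was 0 without 8-week control replicate 2 or 12-week STAM replicate 2 (1764 and 1810 at an unadjusted p under 0.05), 1 without 8-week control replicate 1, 12-week control replicate 1, or 8-week STAM replicate 1 or 3, 3 without 8-week control replicate 3, 8 without 12-week control replicate 2, and 56 without 12-week STAM replicate 1. Arntl lost its call without any 1 array other than replicate 1 of either 12-week group (adjusted p 0.0516 to 0.156), and Tnnc1 without any other than 12-week control replicate 4 or STAM replicate 1 (0.0542 to 0.121). Lrfn3 and Gtf2ird1 lost theirs without any 8-week control, 12-week control replicate 1, 8-week STAM replicate 1 or 3 or 12-week STAM replicate 2 (0.054 to 0.0972 for both), and Klhl7 without the same arrays except 8-week STAM replicate 1 (0.054 to 0.0699). Calls also ended without a dim-probe filter for all 5 (adjusted p 0.0736 to 0.119), with only these groups for Arntl, Tnnc1, Gtf2ird1 and Klhl7 (0.0527 to 0.101), with the slide block for Tnnc1 (0.0582), with slide and row for Tnnc1 (0.0578), with probe means for Gtf2ird1 (0.0531) and with the doubly labelled control at 12 weeks for Gtf2ird1 (0.0847).

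Between 12 weeks and non-tumor tissue at 20 weeks 6 features differed, 1 higher and 5 lower, and 14 with the block. The effect at 20 weeks was lower for the mitochondrial chaperone Clpx (-2.08 ± 0.36), Crip2 (-1.74 ± 0.28), the peroxisomal carnitine transferase Crot (-1.67 ± 0.24) and Gtf2ird1 (-1.22 ± 0.22), with n = 4 arrays per group. Crot held its call without any 1 array. Crip2 lost it without 12-week STAM replicate 2 or 3 (0.0506 to 0.0511), and Clpx and Gtf2ird1 without any array (0.0541 to 0.11 and 0.0592 to 0.146) other than control replicate 4 or non-tumor replicate 2 at 20 weeks, 12-week STAM replicate 1 and, for Clpx, 12-week control replicate 3 or 4 or non-tumor replicate 3 and, for Gtf2ird1, 12-week control replicate 2 or STAM replicate 4. The number was 51 without 12-week STAM replicate 1, 12 without control replicate 4 and 10 without non-tumor replicate 2 at 20 weeks, 2 without 12-week STAM replicate 2 or 3, and 3 without 12-week control replicate 1, control replicate 1, 2 or 3 at 20 weeks or non-tumor replicate 1. The higher share was 16.7%, and 33.3% after normexp. Calls also ended without a dim-probe filter for Clpx and Gtf2ird1 (adjusted p 0.0828 to 0.119), with the doubly labelled control at 12 weeks for all 4 (0.226 to 0.38) and with only these groups for Clpx and Gtf2ird1 (0.101 to 0.192). Between 6 and 8 weeks limma called 0 features, with 1051 at an unadjusted p under 0.05 and 2 with slide as a block.

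Lists were tested for such differences after the data were seen. Camera placed p53 targets higher at 8 than at 6 weeks, where none of 18 passed singly (1 higher adjusted over the list alone) and 16 lay above 0, at a median of 0.58 (adjusted p = 4.12e-07, adjusted p = 0.00252 with an estimated correlation, 7.71e-07 with slide as a block, and at most 3.68e-05 without any 1 array). No slide held all 4 groups. An exact two-sided test of their mean level over 400 permutations of age within condition gave p = 0.035, unadjusted for picking this list. Camera called 14 lists here, also placing matrix, cell cycle and macrophage lists higher and male-biased genes lower (adjusted p = 7.86e-06, 2.12e-05, 5.92e-04 and 5.92e-04). From 8 to 12 weeks it called 16 and from 12 to 20 weeks 9. With an estimated correlation only p53 targets held (other adjusted p at least 0.0834). From 6 to 8 weeks 11 of 100 regroupings called as many lists so, and chance was not excluded.

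Control livers at 20 weeks were compared with those at 6 weeks (n = 4 and 3 arrays). The citrate transporter Slc13a5 rose by 3.07 ± 0.56, the nuclear receptor Nr4a1 by 2.23 ± 0.46, Dkk3 by 1.74 ± 0.29 and the zinc finger gene Zfp979 by 2.58 ± 0.53. Kap fell by 5.21 ± 0.84 on the log2 scale, Zbtb16 changed by -2.86 ± 0.46, the phosphatidate phosphatase Lpin1 by -2.61 ± 0.53, Pdxp by -2.09 ± 0.41 and Eif4ebp3 by -1.93 ± 0.35. Kap was well above background on 1 and Pdxp on 2 of 4 arrays at 20 weeks. The 9 named genes moved the same way within the 3 slides that held both groups, which their pick for groups without overlap ensured. In all 44 features differed, 29 higher and 15 lower, and 135 with slide as a block. The number was 15 and 11 without 6-week replicates 2 and 3, and 29, 18 and 17 without 20-week replicates 1, 2 and 3. Zbtb16 held its call without any 1 array. Leaving out single arrays ended the calls of Dkk3 (6-week replicate 2, adjusted p = 0.0581), Kap (6-week replicate 3, 0.0592), Slc13a5 (6-week replicate 2 or 3, 0.0702 to 0.0897), Eif4ebp3 (6-week replicate 2 or 20-week replicate 3, 0.0578 to 0.144), Lpin1 (6-week replicate 2 or 3 or 20-week replicate 1, 2 or 3, 0.0873 to 0.183), Pdxp (any 6-week array or 20-week replicate 2 or 3, 0.0705 to 0.121), Nr4a1 (any but 20-week replicate 3, 0.0552 to 0.145) and Zfp979 (any array, 0.0578 to 0.167). Calls also ended with the doubly labelled control at 12 weeks for Slc13a5, Zfp979, Nr4a1, Lpin1, Pdxp and Eif4ebp3 (adjusted p 0.0553 to 0.218), with only these groups for all 9 (0.0721 to 0.338), after normexp for Zfp979 and Pdxp (0.0573 to 0.152) and without a dim-probe filter for Zfp979, Nr4a1, Lpin1 and Pdxp (0.0602 to 0.091).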

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

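The tests of other cell types, of tumor tissue against both other tissues, of disease on the clock, of female-biased genes, of directions within slides, of lists between ages and of splits with slide taken into account were chosen only after the results were seen.

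Kupffer cell markers were lower in tumor than in non-tumor tissue, at a median of -3.38. Against low signal or array position, the median was -2.96 without tumor replicate 3 and -3.25 with slide and array row in the fit. Against a lower share of all other liver cells as the whole cause, macrophage markers had a median of 0.0451, T and NK cell markers -0.32, endothelial -0.66 and stellate markers -0.87, and their mean levels differed from that of the Kupffer list by 2.91 ± 0.367, 2.54 ± 0.36, 2.33 ± 0.26 and 2.43 ± 0.40, so a smaller loss of such cells stays open. In both comparisons of tumor tissue, 11 of the 12 markers were lower. A difference specific to tumor tissue, such as fewer resident macrophages or other expression in them, may underlie this as a hypothesis found and tested on the same arrays.

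The score of 3 activating minus 8 output clock genes was higher in STAM liver at 12 weeks by 3.25 ± 0.46, more than in the other comparisons with control (-0.52 to 1.39). If sampling hours differed between groups, control ages might differ too, and an exact permutation test over 14 control arrays gave p = 0.0746, which neither shows the ages alike nor tests STAM against control. An effect of disease was asked through its sign across ages, and the score shifted upward by over 2 standard errors at 2 of 4 ages. Time of day and disease cannot be told apart, because no label used gives the hour of sampling.

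Male-biased genes were lower and female-biased genes higher in STAM liver at 12 weeks and in both tissues at 20 weeks. Against female animals, Xist was well above background on 0 of 32 arrays, and each of the 18 STAM arrays had at least 3 of 4 Y-linked genes above it. Against a loss of all hepatocyte transcripts, the female-biased list had a median of 1.85 at 12 weeks and a mean level higher by 1.80 ± 0.35, although 3 of its 20 members fell, its call ended among genes well above background on all arrays (adjusted p = 0.678) and it had adjusted p = 0.264 with an estimated correlation. A partial loss stays open, as 14 of 26 secreted proteins and 7 of 22 cytochromes fell then, but normexp ended both list calls. The lists moved so in 24 of 24 differences within slides, which restates the pattern. A change in sex-dependent expression with disease stays an untested hypothesis.

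In groups of 4, 1 array stood far from the other 3 in 22 of 406 values tested, where chance gives about 1 in 20. The gap to the nearest array as a share of the range was, for single genes, 0.961 for H19 and 0.88 for Hal on non-tumor replicate 2, 0.895 for Ly6d, 0.927 for Naip1 and 0.842 for Obp2a on tumor replicate 3, 0.857 for Srxn1 on tumor replicate 2, 0.902 for Fgf21, 0.838 for Adgrf1, 0.866 for S100a8 and 0.888 for Tnnc1 on 12-week control replicates 2, 3, 4 and 1, 0.858 for Dbp, 0.836 for Sirt7 and 0.887 for Klhl7 on 12-week STAM replicate 1 and 0.908 for Orm1 on 20-week control replicate 3. For mean levels of lists it was 0.877 for male-biased genes on non-tumor replicate 1, 0.904 for female-biased genes on 12-week STAM replicate 1, 0.926 for Kupffer cell markers and 0.855 for bile acid genes on 20-week control replicate 3 and 0.89 for histone acetylation enzymes and 0.849 for stellate cell markers on tumor replicate 3. The number of probes well above background gave 0.924 for 20-week control replicate 1 and 0.889 for 12-week STAM replicate 2.

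Chance was not excluded for the counts of features whose STAM effect differed from 8 to 12 or 12 to 20 weeks. By limma's test, the STAM effect differed between ages in 9 values of named genes, 8 of which lost the call without 1 array. From 8 to 12 weeks it changed by 4.18 for Arntl, 2.73 for Lrfn3, 2.64 for Tnnc1, 1.39 for Gtf2ird1 and 1.22 for Klhl7, and from 12 to 20 weeks by -2.08 for Clpx, -1.74 for Crip2, -1.67 for Crot and -1.22 for Gtf2ird1. From 6 to 8 weeks the median of p53 targets differed by 0.576.

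Other splits of the arrays were counted, with the real one included. The 10 splits at 6 and at 8 weeks are too few for a share under 0.05, with 491 real and at most 0 other features by limma at 6 weeks, 2565 and 2 at 8 weeks, and 20 and 22 lists at 6 and 25 and 23 at 8 weeks, where 3 and 1 splits gave as many lists. No other of 35 splits was as large for 12 weeks (5392, highest other 128), non-tumor (3448 and 14) or tumor tissue (8249 and 2799). Nor was any for tumor against non-tumor tissue (3172 and 1876) or control ages (44 and 29). Over 100 regroupings no other was as large for features alike in both tissues (2630 and 284) or at all ages (315 and 0). These shares are unadjusted for the number of tests. With 4 of 100 as large from 8 to 12 weeks (15 and 947) and 5 from 12 to 20 weeks (6 and 503), chance was not excluded. From 6 to 8 weeks limma called 0 features (1051 at an unadjusted p under 0.05, highest other 30), so 100 of 100 are as large by construction and nothing was tested. What made some splits call 947 and 503 features was not settled. Among 26453 features with a value on all arrays, 5 of 100 regroupings were as large with slide as a block from 8 to 12 weeks (28 and 116), so chance was not excluded there, and 5 from 12 to 20 weeks (14 and 1001). Without the block the highest others were 936 and 501, so slide alone does not account for both. For counts of lists over 35 splits, no other was as large in non-tumor tissue (29 and 26). Chance was not excluded at 12 weeks (24 and 26, 6 splits), in tumor tissue (24 and 27, 5 splits) or between these tissues (21 and 22, 3 splits). Nor was it over 100 regroupings for differences from 6 to 8 weeks (14 and 21, 33 as large), 8 to 12 (16 and 19, 16 as large) and 12 to 20 weeks (9 and 22, 74 as large). These splits ignore slide. The 8 swaps of groups within slides, with slide as a block, are too few for a share under 0.05, and gave 7940 real and at most 0 other features at 12 weeks, 5634 and 0 in non-tumor tissue, 10392 and 3883 in tumor tissue and 4543 and 1382 between these tissues, and 23 and 25, 27 and 22, 23 and 26, and 21 and 19 lists.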

How the results depend on the processing

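The settings that used slide and array row together, and the slide block and left-out arrays for both counts of genes called alike, and all for p53 targets between ages, were chosen after the data were seen. Of 3019 values of named genes under other settings, 2859 kept direction and side of the threshold, 156 lost the call, 4 gained one and none turned. With 1 array left out, 1682 of 1937 kept both and 255 lost the call. For 89 list results the other settings gave 1238 of 1335 alike, 78 lost, 7 gained and 12 turned, and the left-out arrays 646 of 668 alike, 7 lost, 5 gained and 10 turned. Except where the setting has fewer genes or a stricter threshold by construction, the cause was not tested. Arrays were paired only by slide, since no label used ties samples to an animal. Signal over background limits the dimmest probes: tumor replicate 3 had the lowest array weight, 0.2244.

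These counts of changed features moved by over 1.5 times. Slide as a fixed block gave 892 at 6 weeks, 5655 in non-tumor tissue, 2, 29 and 14 for the differences between successive ages and 135 for control ages. As a random block it gave 918 at 6 weeks, 1, 61 and 18 for the differences and 161 for control ages. Slide with array row gave 2 between 6 and 8 weeks, 11 between 12 and 20 weeks and 94 for control ages. Array weights gave 5559 at 6 weeks, 8228 at 8 weeks, 6708 in non-tumor tissue, 1329 between tumor and non-tumor tissue, 276, 1159 and 48 for the differences and 228 for control ages. Without a filter on dim probes there were 232 at 6 weeks, 1489 at 8 weeks, 0 and 3 for the later differences and 17 for control ages. Where limma gave 0 between 8 and 12 weeks, 2638 had an unadjusted p under 0.05. Genes above background on all arrays gave 36 between 8 and 12 weeks. Normexp gave 313 at 6 weeks, 35 between 8 and 12 and 12 between 12 and 20 weeks, and quantile normalization 1 between 6 and 8 and 36 between 8 and 12 weeks. Trend and robust moderation gave 24 between 8 and 12 weeks. With the doubly labelled control at 12 weeks there were 23, 1 and, for control ages, 14. Only the compared groups in the fit gave 1309 at 8 weeks, 3694 in tumor tissue, 372 between tumor and non-tumor tissue and 1 for control ages. A 2-fold minimum left 1497, 2582, 1820, 4293 and 1636 from 8 weeks to tumor against non-tumor tissue.

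Features called alike in tumor and non-tumor tissue numbered 1425 at 2-fold, 4134 with the slide block and 1313, 1474, 1124, 1163, 970 and 1335 with the controls divided, and those alike at all 4 ages 514 with the block. With 1 array left out, counts ran over 102 to 311, 904 to 2330, 3563 to 5001, 2301 to 3093, 7027 to 9119 and 1857 to 5108 in the 6 comparisons, 0 to 1, 0 to 56 and 2 to 51 for the differences, 11 to 47 for control ages, 1846 to 2921 for both tissues and 86 to 341 for all ages. The mean shift moved by over 1.5 times without 1 array for 5 of 78 called lists: acute-phase proteins in non-tumor tissue (control replicate 3, -1.17 to -0.60), the cell cycle at 8 weeks (STAM replicate 2, 1.15 to 0.76), NRF2 targets in tumor tissue (replicate 1, 0.56 to 0.37) and endothelial (tumor replicate 2, -0.59 to -0.34) and stellate markers (tumor replicate 3, -0.49 to -0.79) between tissues. Called lists ran over 19 to 23, 19 to 27, 23 to 26, 25 to 28, 24 to 27 and 18 to 22. An estimated correlation left 6, 3, 4, 3, 3 and 0 lists, where camera with that correlation had 5 at an unadjusted p under 0.05 in the last, and fry called 10 at 6 and 14 at 8 weeks.

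Some lists turned sign under these settings, with these adjusted p. Pericentral genes in tumor against control had 0.913 after normexp, 0.996 after quantile normalization, 0.983 with the block, 0.718 with weights, 0.962 with slide and row and 0.974 with only these groups, and 0.00843 to 0.997 over left-out arrays. Endothelial markers had 0.939 after normexp, 0.982 with the moved control and 0.788 by fry, and 0.112 to 0.988 over left-out arrays. Histone acetylation enzymes had 0.381 by fry and 0.581 to 0.989 over left-out arrays. In tumor against non-tumor tissue, pericentral genes had 0.675 with weights and 9.13e-05 to 0.904 over left-out arrays, and macrophage markers 0.732 with slide and row and 0.25 to 0.974 over left-out arrays.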

Other observations

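The levels of pericentral genes per array were looked at only after the data were seen. In tumor tissue against control (n = 4 arrays each), enzymes of bile acid and methyl group metabolism fell: Cyp7b1, of the alternative bile acid pathway, changed by -3.45 ± 0.58, the bile acid ligase Slc27a5 by -1.91 ± 0.29 (-1.26 after quantile normalization), the cystathionine synthase Cbs by -1.73 ± 0.18 and the glycine methyltransferase Gnmt by -1.76 ± 0.36. Of 18 bile acid genes, 1 rose and 12 fell, 5 did not pass, with 1 higher and 12 lower adjusted over the list alone, and camera placed them lower (adjusted p = 0.0122, adjusted p = 0.383 with an estimated correlation). Among the 19 one-carbon genes, 2 rose and 11 fell, 6 did not pass (2 higher and 12 lower adjusted over the list alone), and camera placed them lower (adjusted p = 0.00681, adjusted p = 0.376 with an estimated correlation). Of 21 NRF2 targets, 7 rose and 1 fell, 13 did not pass, with 7 higher and 1 lower adjusted over the list alone, and camera placed them higher (adjusted p = 0.017, adjusted p = 0.421 with an estimated correlation). Cbr3 rose by 4.00 ± 0.61 and Srxn1 by 1.99 ± 0.28. Without tumor replicate 3 the bile acid call ended (adjusted p = 0.0575) as it did after normexp (0.0809) and quantile normalization (0.108), and without tumor replicate 1 the NRF2 call ended (0.0951).

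The mean level of pericentral hepatocyte genes differed between tumor arrays, at 3.46, 3.85, 0.334 and 5.77 on tumor replicates 1 to 4, against 3.28 to 4.24 in non-tumor tissue and 3.66 to 3.9 in control.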
